A study of Mus musculus with 6 samples.

How the data were processed

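Total RNA from 6 cultures of mouse mesenchymal stem cell clones was hybridised to Affymetrix exon arrays, 1 array per clone, after biotin labelling by a whole-transcript sense target protocol. Per the labels' protocols, the cells came from hindlimb bone marrow of a mouse with floxed Dicer alleles, were immortalised with SV40 large T antigen, and were cloned. Dicer is the ribonuclease that cuts microRNA precursors to their mature length. The Dicer-null clones were made by infection with an adenovirus carrying Cre recombinase and GFP, sorting for GFP and cloning again, and their deletion was tested by genotyping PCR, per the labels' protocols.

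The deposited table held log2 values for 44343 transcript clusters, 1 column per array. The submitters' processing notes name Partek 6.5 and RMA, a method that corrects background, brings arrays to a common distribution and summarises probes, and they give no role or order. The genome build behind these values is not given in the sources used here. The values of each array spanned about 1.80 to 14.1 and the array medians lay between 3.01 and 3.21, as log2 RMA values do. Because RMA equalises the arrays, a change in total RNA per cell would not be seen. Scanner files and detection calls were not used here, so no gene is called absent, and the number of arrays limits the precision.

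Arrays were grouped by their titles and genotype labels into 2 Dicer-carrying clones, labelled 6 and 12, and 4 Dicer-null clones. The series design text calls the null clones derivatives of the Dicer-carrying ones, and the clone numbers tie 6.8 and 6.9 to clone 6, and 12.2 and 12.4 to clone 12. The array titled as clone 6.9 carries a cell type label of clone 6.8. The title was followed, and its values differed from those of clone 6.8. Sibling null clones share 1 parental array, and nothing says that any clone was cultured more than once, so p-values measure the spread between clones.

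Gene names came from the platform annotation of the probe table and were updated by Entrez identifier to the gene table of mouse assembly GRCm38.p6, which 22485 of 22781 clusters matched. Of the clusters, 22781 were listed with 1 gene, 2085 with several and 19477 with none in that table. Clusters with several genes were not used for naming, and each gene was represented by its cluster with the highest mean over the 6 arrays. This left 18997 genes, of which 18774 had a chromosome. No coordinates are given, because the assembly behind the array values is not known.

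Differences were tested with limma 3.58.1 in R 4.3.3, by a linear model with the parental line as a fixed block and Dicer loss as the tested term, moderated by empirical Bayes over 3 residual degrees of freedom, with Benjamini-Hochberg adjustment over all 18997 genes and a threshold of 0.05. The block was chosen before the data were examined, because each null clone derives from one of the Dicer-carrying clones. As a check of this pairing, the difference between line 12 and line 6 in the Dicer-carrying arrays was compared across genes with that in the null clones, and the correlation was 0.16 over 5409 genes with a mean above 6. That correlation is across genes, which are not independent replicates. With the line as a random block the consensus correlation of arrays of 1 line was -0.13, so the values gave little sign of a shared line effect. The unblocked fit is given beside each result whose call it changes.

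The response of the lines to Dicer loss was compared with an interaction contrast of 4 cell means, on 2 residual degrees of freedom. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. With an estimated correlation camera judges a list on the 3 residual degrees of freedom of the fit, and with a preset one on far more. A call lost with the estimated correlation thus need not come from correlation between genes. Benjamini-Hochberg adjustment was over 20 lists of 312 genes fixed before the data were examined, 275 of them measured. The lists covered reported let-7 targets, oncofetal genes, imprinted growth genes, miRNA biogenesis and Argonaute genes, miRNA host transcripts, reported extracellular matrix targets of miR-29, Hox genes, pluripotency and germline genes, cell cycle genes, p53 targets, interferon response genes, NF-kB cytokine and chemokine genes, and unfolded protein and amino acid stress genes. Cell type lists covered mesenchymal stromal, osteoblast, adipocyte, chondrocyte, smooth muscle, haematopoietic and endothelial markers.

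The genes named were chosen by rule before the data were examined. They are Dicer1, Nr6a1, the 8 highest and the 8 lowest changes among genes past the threshold that moved the same way in all 4 null clones, up to 4 members of each list past the threshold, and otherwise the member of that list with the largest change. Predicted genes without a name were skipped. Other genes were chosen after their values were seen, and are named so in the text.

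The fit was tested on simulated data with the 18997 genes of the real arrays, in which 200 genes were changed by known amounts over 5 simulations. It recovered 23.3% of genes changed by 1 log2 unit, 75.2% of those changed by 2 and 93.3% of those changed by 4, and 6.31% of the calls were false. The simulated spread was drawn from the model of the fit itself, independent across genes and clones, without a floor or chromosome-wide shifts. These shares hold under those assumptions and need not hold for the real arrays. Alternatives fixed before the data were examined were the fit without the block, the line as a random block, the mean of sibling clones, leaving out the dimmest 30% of genes, a further quantile normalisation, centring of arrays, an intensity trend with robust moderation, the mean of all clusters of a gene, and leaving out each array. Testing every transcript cluster and centring genes on their chromosome were added after seeing the data. A planned test of let-7 seed matches over 26 microRNA families in 3′ untranslated regions was not run, because no transcript sequence was used here. Figures were drawn with matplotlib 3.10.9.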

Results

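RNA was measured on 6 arrays of undifferentiated, untreated cultures of mouse bone marrow mesenchymal stem cell clones. Clones 6 and 12 carried Dicer (n = 2). Their derivatives lacked it (n = 4), with clones 6.8 and 6.9 from line 6, and clones 12.2 and 12.4 from line 12. Log2 changes are given as Dicer-null minus Dicer-carrying, with the standard error of the fit. No array was of a Dicer-carrying clone that had been infected, sorted and cloned again, so those steps cannot be separated from Dicer loss. Dicer1 itself, averaged over the probes of its single transcript cluster, had log2 levels of 4.48 and 4.83 in Dicer-carrying clones 6 and 12, 4.66 and 4.43 in null clones 6.8 and 6.9, and 4.47 and 4.64 in null clones 12.2 and 12.4. The cluster does not measure the deleted part by itself, so it checks no label.

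The first comparison asked which genes differed with Dicer loss. Igf2bp1, an oncofetal RNA-binding protein and reported let-7 target, rose in its brightest transcript cluster from a mean log2 level of 2.84, near the floor of the arrays, to 8.43, a change of 5.59 ± 0.44. With the mean of its 3 clusters the change of Igf2bp1 was 2.99, with an adjusted p of 0.0703 in limma. Ifitm5, an osteoblast membrane protein, fell from 8.59 to 2.99, a change of -5.61 ± 0.11. Phex, an endopeptidase needed for phosphate handling in bone, changed by -5.25 ± 0.14, and the citrate transporter Slc13a5 by -5.69 ± 0.37.

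The transcripts that rose also included Tgm2, a protein crosslinking enzyme, at 3.88 ± 0.35, and Tgfbi, a matrix protein induced by TGF-beta, at 3.41 ± 0.27. The kinase Sik1 rose by 3.10 ± 0.26, the p53-induced gene Btg2 by 2.64 ± 0.28 and the kinase gene Uhmk1 by 2.58 ± 0.20. Mov10, a helicase that binds Argonaute proteins, rose by 2.57 ± 0.25 and Plscr2 by 2.70 ± 0.16. Among transcripts that fell, the proprotein convertase Pcsk6 changed by -5.57 ± 0.19, the elastic fibre protein Fbln5 by -5.32 ± 0.17 and Galnt3, a glycosyltransferase that protects FGF23, by -4.90 ± 0.22. Tmem45a changed by -4.83 ± 0.17 and the matrix protein Tnn by -4.73 ± 0.43. Adjusted p in limma with Benjamini-Hochberg adjustment was 0.0305 for Igf2bp1 and 0.00225 for Ifitm5. It was 0.0187 for Plscr2 in limma, 0.263 without the parental block and 0.401 with the line as a random block. With the mean of the sibling clones Tgfbi, Ifitm5, Fbln5, Phex and Galnt3 still passed in limma. Igf2bp1, Tgm2, Sik1, Plscr2, Btg2, Uhmk1, Mov10, Slc13a5, Pcsk6, Tmem45a and Tnn did not. That fit gave the same log2 changes and has fewer residual degrees of freedom than the main fit, so a miss there need not mean a smaller change.

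In all, 112 of 18997 genes passed in limma, 31 higher and 81 lower, and all 112 had the same sign in all 4 null clones. To pass, a gene needs a change that is large beside the spread of these same clones, so this agreement was largely set by the selection. Over all genes 32.1% had the same sign in all 4, where 22.2% would if parental and null arrays were interchangeable. The median over genes was 3.70 and 3.75 on the parental arrays and 3.62 to 3.67 on the null arrays. An offset between arrays can thus add to the excess, which does not count the genes that respond. The genes that rose had a median change of 1.79 and the genes that fell one of -1.93. In 63 of the 81 lower genes the null mean was below a log2 level of 4. Of the 81, 17 lay on chromosome 9, where the median change of expressed genes was -0.47 and the median of clone 12 minus clone 6 was 0.39, both relative to all expressed genes. Without the parental block limma called 220 genes, 67 higher and 153 lower, and 90 genes were called by both fits. Leaving out a parental array leaves its null clones without a reference, and limma then called 0 genes without clone 6 and 0 without clone 12, with 1654 and 1493 genes at an unadjusted p under 0.05. The count was 12 without clone 6.8, 13 without 6.9, 17 without 12.2 and 2 without 12.4. With a further quantile normalisation Tgm2, Tgfbi, Plscr2, Btg2, Tnn, Tnrc6a, Lamc1 and Tnfaip3 missed the threshold. With the arrays centred Btg2 and Mov10 missed it, at an adjusted p of 0.0508 and 0.0502 in limma, and Btg2 had 0.0514 with the mean of all clusters and 0.0594 after centring on the chromosome.

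**Figure D1:**
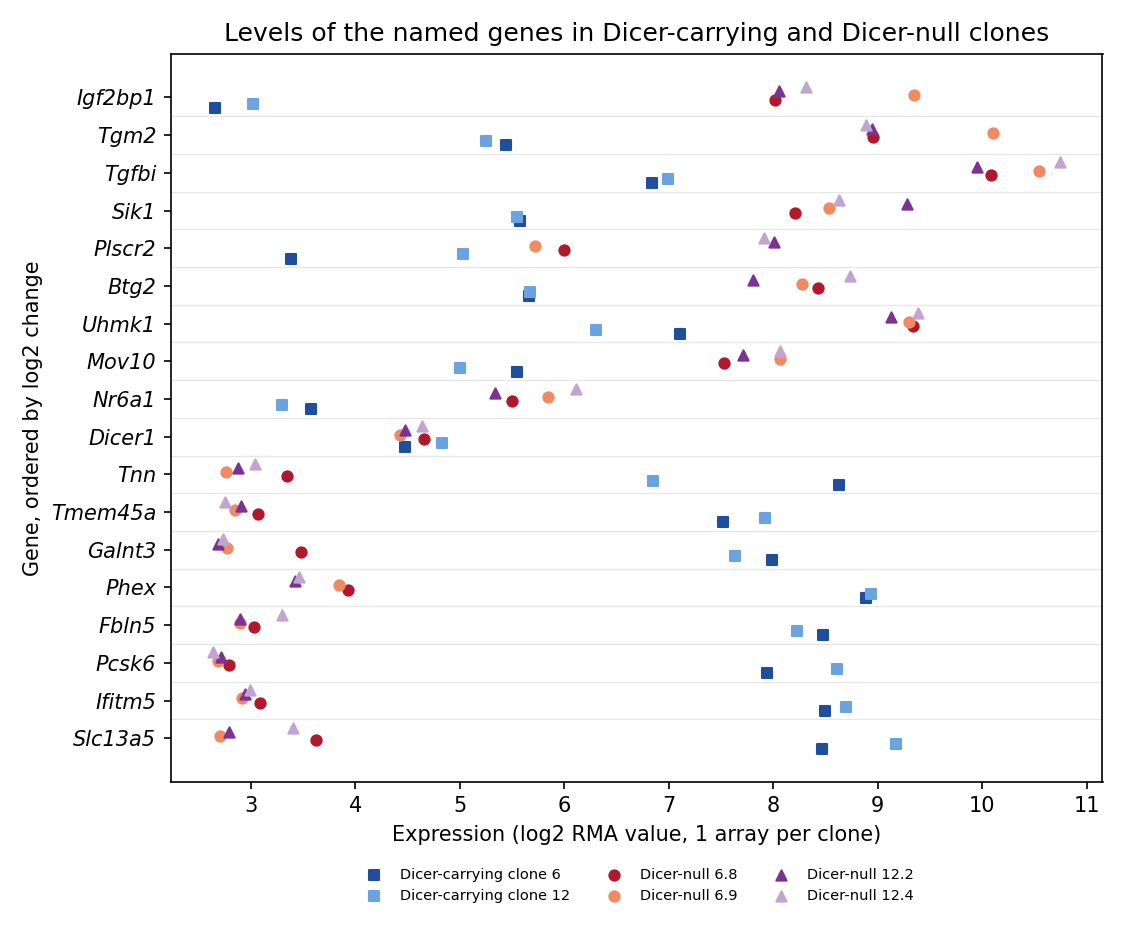
Log2 RMA level of each gene on each of the 6 arrays, 1 point per clone, with squares for the Dicer-carrying clones and circles and triangles for the Dicer-null clones of line 6 and line 12. Igf2bp1 has a mean of 2.84 in Dicer-carrying and 8.43 in null clones, while Ifitm5 has means of 8.59 and 2.99.

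Nr6a1, the nuclear receptor gene in the study's title, and the targeted gene were fixed in advance. Dicer1 had a log2 level of 4.65 ± 0.25 (SD, n = 2) in Dicer-carrying and 4.55 ± 0.12 (SD, n = 4) in null clones, a difference of -0.10 ± 0.14 with an adjusted p of 0.885 in limma. Nr6a1 had a level of 3.44 ± 0.20 (SD, n = 2) against 5.70 ± 0.35 (SD, n = 4). Its changes were 1.92 and 2.27 in clones 6.8 and 6.9, and 2.04 and 2.81 in clones 12.2 and 12.4, with a mean of 2.26 ± 0.26 and an adjusted p of 0.0548 in limma, above the threshold. Without the parental block limma gave Nr6a1 an adjusted p of 0.0236. It was 0.0283 in limma with the line as a random block and 0.0375 with the dimmest genes left out. With the mean of the siblings it was 0.0651, and with a further quantile normalisation 0.0661.

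Reported let-7 targets were the next question, since the title names let-7, a microRNA family that represses genes of early development. Of 27 measured members 1, Igf2bp1, rose over all genes tested and 0 fell. Adjusted over the list alone, 7 rose and 2 fell. The 7 were Igf2bp1, Nr6a1, Arid3a, Nras, Cdk6, Plagl2 and E2f6, and the 2 were Mycn and Plagl1. Of members chosen after their values were seen, Hmga2 had a change of 2.30 ± 0.81, Arid3a one of 1.86 ± 0.33, the cell cycle kinase Cdk6 one of 2.06 ± 0.37 and Plagl1 one of -2.44 ± 0.64. The list had a median of 0.35 and moved up with an adjusted p of 0.000294 in camera. With an estimated correlation, and so on 3 residual degrees of freedom, its adjusted p was 0.294 in camera. That estimate was -0.0019, below the preset 0.01, so it does not account for the higher p. The study names let-7 and Nr6a1 in its title, so the list is not independent evidence of its direction.

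Osteoblast markers were a list fixed in advance. Of 8 measured members 1, Phex, fell over all genes and 0 rose, and Phex and Dmp1 fell when adjusted over the list alone. Members chosen after their values were seen were the sialoprotein Ibsp at -5.38 ± 1.69, the transcription factor Dlx5 at -3.46 ± 1.28, and the alkaline phosphatase Alpl at -2.19 ± 1.63, none past the threshold. The list median was -2.93, with -1.97 and -2.35 in clones 6.8 and 6.9 and with -5.23 and -2.04 in clones 12.2 and 12.4. The adjusted p was 9.11e-05 in camera, and 0.294 in camera with an estimated correlation. The estimate was 0.144, above the preset 0.01, but camera then also used the 3 residual degrees of freedom. The higher p thus does not measure the correlation alone. Smooth muscle markers had a median of -0.59 with 0 of 12 members past the threshold over all genes or the list alone. Their adjusted p was 0.0663 in camera and 0.779 with an estimated correlation, and the largest change was that of Actg2 at -2.64 ± 0.62.

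Genes of the microRNA pathway included Tnrc6a, a scaffold of the silencing complex, which rose by 2.30 ± 0.20 with an adjusted p of 0.0338 in limma, and 0.0704 with the mean of the siblings. It was 1 of 13 measured members past the threshold over all genes, and 0 fell. Adjusted over the list alone, 4 rose, Tnrc6a, Tnrc6b, Ago2 and Tarbp2. Tarbp2, a partner of Dicer chosen after its values were seen, had a change of 1.05 ± 0.16. Its adjusted p was 0.0862 in limma, and 0.0496 in limma without the block. The list median was -0.01 and its mean 0.39, and camera gave an upward adjusted p of 0.038, which was 0.376 with an estimated correlation. That estimate was -0.065, below the preset 0.01, so it does not account for the higher p. Without 1 array the adjusted p of this list in camera was 0.0666 for clone 6, 0.0845 for clone 12, 0.0662 for 6.8 and 0.197 for 12.4, and it was 0.143 with the arrays centred. It was 0.09 in camera with the mean of the siblings, 0.0539 with the dimmest genes left out, 0.0519 with a further quantile normalisation and 0.0502 after centring on the chromosome.

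Genes of p53, NF-kB and interferon responses had medians above 0. Of 18 p53 targets 1, Btg2, rose over all genes and 0 fell, and Btg2, Zmat3 and Tnfrsf10b rose over the list alone. Cdkn1a, the main cell cycle inhibitor among them and chosen after its values were seen, had a change of -0.36 ± 0.22. Mdm2, also chosen so, was the 1 member lower in all 4 null clones, at -0.48 ± 0.30, and 5 members were higher in all 4. The cells carried SV40 large T antigen, and p53 activity was not measured. The p53 list had a median of 0.26 and an adjusted p of 0.00336 in camera, and 0.294 with an estimated correlation. Here too the estimate, -0.034, was below the preset 0.01 and does not account for the higher p. Of 14 NF-kB genes 1, Tnfaip3, a feedback inhibitor of that pathway, rose over all genes and over the list alone, by 1.66 ± 0.12. With the mean of the siblings the adjusted p of Tnfaip3 was 0.0704 in limma. That list had a median of 0.78, with 0.24 and 0.01 in clones 6.8 and 6.9 and with 1.82 and 0.18 in clones 12.2 and 12.4. It had an adjusted p of 0.00336 in camera, which was 0.779 with an estimated correlation and 0.464 without clone 12. Of 15 interferon response genes 0 passed over all genes or the list alone, and Rsad2 had the largest change at 2.87 ± 1.09. The interferon list had a median of 0.69, with 0.22 and -0.16 in clones 6.8 and 6.9 and with 2.12 and 0.57 in clones 12.2 and 12.4. Its adjusted p was 0.0359 in camera, 0.958 with an estimated correlation, 0.19 with the arrays centred, 0.0735 with a further quantile normalisation, 0.126 without clone 12.2, and 0.775 with the opposite sign without clone 12.

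The remaining lists did not pass in camera. Oncofetal genes had an adjusted p of 0.191 in camera, a median of -0.03 and a mean of 0.77, with Igf2bp1 the 1 of 16 members that rose over all genes. Over that list alone Igf2bp1 and Nr6a1 rose and Mycn fell. Imprinted growth genes had a median of -0.19, a mean of 0.02 and an adjusted p of 0.92 in camera, and Mest differed by 3.19 ± 2.29, with 7.46 in clone 12.4 and -0.38 in clone 12.2. Host transcripts of microRNAs had a median of -0.05, a mean of -0.14 and an upward camera sign at an adjusted p of 0.92. Unfolded protein and amino acid stress genes had a median of -0.18, a mean of 0.10 and a downward camera sign at an adjusted p of 0.884, and over the list alone Dnajb9 rose while Xbp1 and Herpud1 fell. Reported matrix targets of miR-29 had an adjusted p of 0.884 in camera, and Lamc1, a laminin chain, rose by 1.17 ± 0.12. The adjusted p of Lamc1 was 0.0436 in limma and 0.119 without the block, and Lamc1 also missed the threshold with the line as a random block, with the mean of the siblings, with the dimmest genes left out, with trend and robust moderation and after centring on the chromosome. Over the list alone Lamc1 and Col3a1 rose and 4 others fell.

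Mesenchymal stromal markers had an adjusted p of 0.884 in camera, with 0 of 14 past the threshold over all genes. Vcam1, an adhesion receptor, had a change of 3.16 ± 0.37 at an adjusted p of 0.0548 in limma. That p was 0.0347 with the dimmest genes left out, 0.118 without the block and 0.194 with the line as a random block. Over that list alone Vcam1 rose and Cspg4 fell. Chondrocyte markers had an adjusted p of 0.304 in camera, and Col2a1 and Col11a1 fell over the list alone. Adipocyte markers, Hox genes, and cell cycle genes had adjusted p of 0.884, 0.884 and 0.92 in camera. Pluripotency and germline genes had 0.801 in camera. Their largest members were Lpl at -1.08 ± 1.19, Hoxa9 at 1.25 ± 0.28, Ccne1 at 1.08 ± 0.31 and Klf4 at -1.47 ± 0.44, none past the threshold. Haematopoietic and endothelial markers, which cultures of marrow cells could hold, had medians of 2.83 and 2.61 in their mean levels over the 6 arrays. No member had a mean over the arrays above 4.14. Both had an adjusted p of 0.92 in camera, and Cd68 differed by 0.27 ± 0.22 and Egfl7 by -0.25 ± 0.14.

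**Figure D2:**
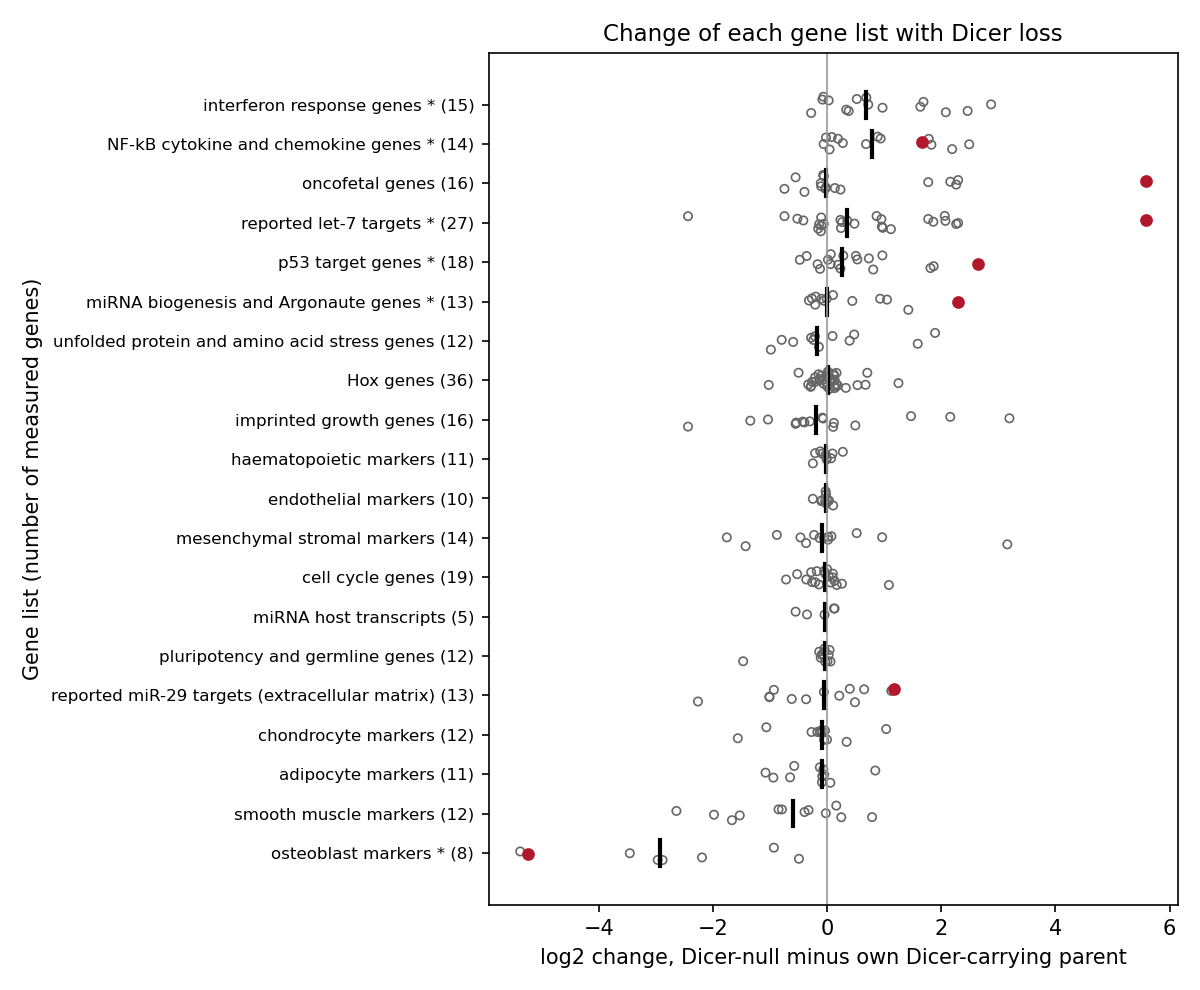
Log2 change of each measured member of the 20 gene lists, Dicer-null minus own Dicer-carrying parent, with 1 point per gene, the list median as a black bar and genes past the limma threshold filled in red. Lists with an asterisk passed in camera at the preset correlation, and osteoblast markers have the lowest median, -2.93.

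The last comparison set the responses of line 6 and line 12 side by side. Across 5409 expressed genes the mean changes of line 6 and line 12 correlated at 0.64, and the changes of clones with no shared array correlated at 0.47 to 0.60. Of 724 genes changed by over 1 log2 unit in both lines, 691 or 95.4% had the same direction. These values are across genes, which are not independent replicates. The interaction test had 1 Dicer-carrying array per line and 2 residual degrees of freedom. A count of 0 in it cannot show that the lines respond alike. The interaction test in limma called 0 genes as different between the lines in their response, with 569 at an unadjusted p under 0.05. The line term of the blocked limma model called 0 genes as different between the lines themselves, with 999 at an unadjusted p under 0.05, and both counts stayed 0 in each alternative run. The Dicer-carrying clones correlated with each other at 0.94, the null clones at 0.79 to 0.92 and null with Dicer-carrying clones at 0.74 to 0.87. Sibling null clones were not the most alike, at 0.87 for 6.8 and 6.9 and 0.82 for 12.2 and 12.4.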

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

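The tests of a few strongly changed genes, of expression level on both chromosomes, of array-wide scaling and of blood cell RNA were chosen after the result was seen. By Dixon's test at the 95% level, which chance meets in about 1 in 20 groups, 58 named genes and 20 gene lists were examined over the 4 null clones, and 8 values stood apart.

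Tgm2 had a log2 level of 10.1 in clone 6.9, above the other null clones. Galnt3 had 3.48 in clone 6.8 and Mef2c, a transcription factor gene chosen after its values were seen, had 3.56 there, both above the other null clones. H19, an imprinted RNA, had 5.98 in clone 6.9 against lower values in the other null clones. The median change of p53 targets was 0.13 in clone 6.9, below the other null clones. Usp18, an interferon-induced protease, differed by 3.89 in its change between line 12 and line 6, with an adjusted p of 1 in limma, and had parental levels of 6.70 in clone 6 and 3.45 in clone 12, so most of that contrast lies in the parental arrays. Smooth muscle markers had a median of -0.81 and osteoblast markers one of -5.23 in clone 12.2, both below the other null clones. The median change of chromosome 14 genes relative to all expressed genes was higher by 0.59 in the line 12 clones than in the line 6 clones, of opposite sign in the lines, a difference not tested across clones. The parental clones differed by -0.50 on chromosome 14, clone 12 minus clone 6, so most of that contrast lies in the Dicer-carrying arrays.

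Relative to all expressed genes, the median change of 257 of them on chromosome 9 was -0.46 and -0.51 in clones 6.8 and 6.9 and -0.61 and -0.29 in clones 12.2 and 12.4, and that of 138 of them on chromosome 12 was 0.53, 0.62, 0.39 and 0.27 in the same order, each at a permutation p of 1e-04 across genes, the smallest the permutations can give. The Dicer-carrying clones themselves differed there, clone 12 minus clone 6 having a median of 0.39 on chromosome 9 and -0.09 on chromosome 12. Argued against were a few strong genes, since 83.7% of chromosome 9 genes lay below and 81.9% of chromosome 12 genes above the median of all, with random limits of 57.6% and 60.1%, and a bias with level, since at most 0.01% of level-matched draws, the smallest share they can give, reached chromosome 9 or chromosome 12. A gain or loss of whole chromosomes, in null or parental clones, may account for them, since the weakest of 3 blocks in gene order was -0.36 on chromosome 9 and 0.38 on chromosome 12, beyond limits of -0.13 and 0.17, but DNA was not measured and an effect of Dicer loss stays untested. After centring on the chromosome 85.7% of the called genes were called again. Centring moved only genes above a log2 level of 6 on some array. The shifts were also small beside the median changes of called genes, 1.79 for those that rose and -1.93 for those that fell. So this share was largely set in advance, and it does not show which called genes follow from the shifts.

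The NF-kB list had a median of 1.82 in clone 12.2, above the other null clones, and the interferon list had 2.12 there, against a parental clone 12 that itself lay at -1.04 relative to clone 6 in that list. Blood cells in that culture are argued against, since haematopoietic markers had a median change of -0.034 in clone 12.2. In the NF-kB list the parental clones differed by a median of 0.01. Clone 12.4, compared with the same parental array, had 0.18 in the NF-kB list and 0.57 in the interferon list. The parent thus does not account for the gap between clones 12.2 and 12.4. What sets clone 12.2 apart, and the share of the parent in the interferon values, stay open, and no biological explanation was tested.

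Of the clusters without a listed gene, 12.5% exceeded a log2 level of 6 in clone 6.9 against 6.16 to 7.98% on the other arrays. In the normalised values, signal added to all clusters alike is argued against, since 68.9% of them were brighter in clone 6.9 than the mean of the other null clones. Array-wide scaling of these values is argued against too, since 26.2% of listed clusters exceeded 6 in clone 6.9, within the range of 25.7 to 26.9% on the other arrays. RMA corrects background and brings arrays to a common distribution, so neither test can judge such effects in the raw signal. What these clusters measure is not known here, so RNA quality or DNA in that sample may still account for it, and no biological explanation was tested.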

How the results depend on the processing

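Testing all transcript clusters and centring on the chromosome were chosen after the result was seen. All 112 called genes kept their sign with a further quantile normalisation, with centred arrays, with the mean of all clusters of a gene and after centring on the chromosome. Other alternatives could not turn it, as these genes had 1 sign in all 4 null clones, or did not compare it. The limma count of 112 (31 genes higher in Dicer-null clones, 81 genes lower in Dicer-null clones) was 220 (67, 153) with no replicate block, 233 (64, 169) with trend and robust moderation, 47 (15, 32) with a further quantile normalisation, 15 (3, 12) with the mean of the sibling clones, and 33 (4, 29) with all clusters tested. Higher genes were 56 with the dimmest 30% left out, where fewer genes are tested, and 20 with the mean of all clusters of a gene. With 1 array left out the counts ranged from 0 to 17, higher from 0 to 3 and lower from 0 to 15, with fewer arrays for the spread. For other alternatives the cause was not tested. The counts were 129 with the line as a random block, 98 with centred arrays and 129 after centring on the chromosome. Of 9 choices of 1 reference array per line, 1, the real one, gave 112 genes and the highest other 1. Such a set of 9 choices is too small for a share under 0.05. Every other choice also places a Dicer-carrying array among the nulls, which adds any real difference to the spread. Few calls there were thus likely in advance. Gene lists past the threshold in camera were 6, and 0 with an estimated correlation, 4 with quantile normalisation, 5 with the dimmest genes left out, with centred arrays or after centring on the chromosome, and 3 to 6 with 1 array left out. For the let-7, microRNA pathway and p53 lists the estimated correlation was below the preset value, so it does not account for their loss. The loss in these lists comes from the fewer degrees of freedom, 3, that camera uses with an estimated correlation. In the other lists that lost a call there, the correlation and the degrees of freedom both changed. The camera adjusted p of interferon response genes ranged from 4.96e-05 to 0.775 with 1 array left out, and their sign reversed at 0.775 without clone 12. Smooth muscle markers passed in camera with the mean of the siblings, with centred arrays and without clone 6, 6.8 or 12.4. Without the block no list call changed, and Plscr2, Lamc1 and Tnip1 lost and Nr6a1 and Tarbp2 gained a call. Over all alternatives 718 values of named genes kept their sign and side of the threshold, 140 lost and 9 gained a call. The 718 include genes not called in the main fit, which had no call to lose. Each called named gene had 15 alternatives, and lost its call in 2 for Ifitm5 and Fbln5 up to 13 for Lamc1. In genes not called 3 values reversed without clone 12. With 1 array left out Dicer1 ranged from -0.27 to 0.067, H19 from -1.44 to 0.33 and Usp18 from -0.31 to 3.58. Of the list values 27 reversed, those but interferon in lists that did not pass. In camera the adjusted p of reversed lists was 0.913 for miRNA host transcripts with the mean of the siblings, 0.748 for them and for haematopoietic markers with the dimmest genes left out, 0.888 for cell cycle genes and 0.906 for haematopoietic markers with quantile normalisation, 0.839 for haematopoietic and 0.781 for endothelial markers with centred arrays, and 0.781 for miRNA host transcripts and 0.809 for haematopoietic markers with the mean of all clusters. Lists that reversed with 1 array left out had adjusted p in camera of 0.727 to 0.976 (imprinted growth genes), 0.727 to 0.952 (miRNA host transcripts), 0.312 to 0.976 (mesenchymal stromal markers), 0.0812 to 0.942 (adipocyte markers), 0.727 to 0.978 (Hox genes), 0.738 to 0.976 (cell cycle genes), 0.732 to 0.933 (haematopoietic markers) and 0.732 to 0.962 (endothelial markers). The let-7 seed-match test was not run. Levels near the floor of the arrays, as in many lower genes, limit the size of the falls.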

Other observations

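All genes of this part, and their grouping, were chosen after the result was seen. Mef2c, a transcription factor, changed by -4.70 ± 0.18 with an adjusted p of 0.00584 in limma. Dlx3, a homeobox gene, changed by -2.15, Bmp8a by -2.12, Col11a2 by -2.47, Col22a1 by -1.60 and Sgms2, a sphingomyelin synthase, by -2.97, each past the threshold in limma. Bambi, a decoy receptor for BMP and TGF-beta, changed by -2.74 and the Wnt deacylase Notum by -1.05. No enrichment was tested for these genes.

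Tnip1, which binds the NF-kB inhibitor encoded by Tnfaip3, rose by 1.79 ± 0.19 with an adjusted p of 0.0481 in limma. In limma Tnip1 had an adjusted p of 0.0628 without the block, 0.0508 with centred arrays, 0.0743 with a further quantile normalisation, 0.102 with the line as a random block, 0.0765 with the mean of the siblings and 0.0514 with the mean of all clusters. Zfp568, a zinc finger repressor of a placental Igf2 transcript, rose by 2.43, and Lgr6, a receptor of R-spondins, by 1.95. Chemokine genes differed among clones, with Ccl2 at 5.66 in clone 12.2 and -0.01 in clone 6.9, and Cxcl10 at 5.80 and 0.12.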
